A study of Rattus norvegicus with 6 samples.

How the data were processed

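The series holds 6 arrays of cultured rat skeletal muscle-derived stem cells from males, 1 per group, with groups taken from the sample titles: cholesterol, fatty acid, high glucose control, low glucose control, LZ serum and OZ serum. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Plus Micro kit and analysed on Affymetrix Rat Gene 2.0 ST arrays by a core laboratory. The cholesterol concentration, 100 mg/dl, is the only dose in the labels. The titles LZ and OZ are used as given.

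The deposited values are probe-set intensity values on a linear scale, 1 per probe set and array, for 36685 probe sets. Their summary method, background correction and normalization are not given in the sources used here. The arrays had nearly equal distributions, with median intensities from 104.6 to 109.2 and 95th percentiles from 2223 to 2288, so the values were taken as already scaled to each other, and any true difference in total RNA between cultures was not measurable. No values were centred by gene: every value was positive, with a lowest value of 3.63. No pair of arrays held more than 32 identical values, so none is a copy of another. Log2 was taken without an offset.

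Probe sets were named through the platform annotation. It gives 1 gene for 18511 probe sets, several for 575 and none for 17599, and probe sets with several genes or none were not used. Of the Entrez identifiers, 18394 were found in a RefSeq gene table of assembly GRCr8, which changed 0 symbols and from which no coordinates were used. A gene with several probe sets (291 genes) took the one with the highest mean. This left 18166 genes, of which 11540 had a mean over the 6 arrays at or above the median of all values, log2 6.74 or an intensity of 107.2. Some genes of the fixed panel are not reported here.

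All choices of comparisons, lists, thresholds and named genes were made before the data were examined, except where stated. With 1 array per group there was no test and no p-value. A gene's value against several reference libraries is the smallest of its log2 differences when all have the same sign and 0 otherwise, and it was counted at 2-fold or more. The 6 comparisons were cholesterol against both controls, fatty acid against both controls, cholesterol against fatty acid, OZ against LZ serum, high against low glucose control, and both serum libraries against both controls. Gene lists, 30 in number with 582 genes, of which 427 passed the signal filter, cover lipid, stress, inflammatory, growth, muscle, matrix and energy pathways and markers of other cell types. For lists with at least 3 measured genes, the median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins. These percentiles describe the libraries. The overlap of both lipids with separate controls was added after seeing the data.

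Genes named in the text were drawn, in each comparison, from up to 12 with the largest positive and 12 with the largest negative differences of at least 2-fold. Further sources were up to 4 genes with the largest differences from each list and a fixed panel of 30 genes, 26 of them annotated. Symbols that are only provisional or belong to receptor and small RNA families were passed over. The genes listed as shared by the lipids and those in the closing observations outside this rule were chosen after their values were seen.

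The counting rule was tested on simulated data for cholesterol against both controls with noise drawn from the difference between the controls. Over 11540 genes, it recovered 0% of genes changed 1.5-fold, 34% of those changed 2-fold and 100% of those changed 3-fold or 4-fold. The low rates at 1.5-fold and 2-fold follow from the threshold of 2-fold, which must be passed against both controls. Of 11340 unchanged genes the rule called 5, against 24 with 1 control only. The difference between the controls also holds the effect of glucose, so this noise is not a measured replicate error. Of lists drawn at random from the simulated genes, 2.0% lay outside the middle 95%. A low rate was set by construction, as the simulated genes varied independently, and it does not carry over to genes regulated together.

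Alternatives were quantile normalization, centring on the median, cyclic loess, no signal filter, a stricter filter (highest of the 6 arrays at or above the 75th percentile, log2 8.68), the mean of a gene's probe sets, a 1.5-fold threshold, each control or serum library alone and the mean of the controls. An offset of 32 before log2 and agreement with the serum libraries as well were added after seeing the data. Under every alternative scaling the median of all differences stayed within 0.1 of 0 in each comparison. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.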

Results

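Gene expression was measured in stem cells isolated from the skeletal muscle of male rats and grown in culture. These are adherent progenitor cells obtained by plating. Total RNA was hybridised to Affymetrix Rat Gene 2.0 ST arrays, on which a probe set is a group of short oligonucleotides read together as 1 value. The series holds 6 libraries with 1 array each. They are titled cholesterol, fatty acid, high glucose control, low glucose control, LZ serum and OZ serum. The cholesterol cells received 100 mg/dl cholesterol with cyclodextrin as its carrier, and the labels name sodium palmitate, the salt of a saturated fatty acid, as the other lipid. The labels give no dose for palmitate, do not say whether either control held cyclodextrin, and do not say which control belongs to which treatment, so each lipid library was read against both controls. There are no replicates: no value has an error, no test was possible, and each difference describes these libraries and not the conditions. The number of arrays limits the precision. Median intensity over the 36685 probe sets ran from 104.6 to 109.2 across libraries. Of 18166 named genes, 11540 passed a filter on mean signal, and a gene was counted when it was at least 2-fold higher or lower than every reference library.

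The cholesterol and fatty acid libraries stood apart from the other four. The fatty acid library differed at least 2-fold from the high glucose control in 472 genes and from the low glucose control in 427. The cholesterol library differed from these controls in 232 and 216 genes. The controls differed from each other in 41 genes, and the LZ serum library differed from the high glucose control in 3. In a principal component analysis, the first component held 56.1% of the variance with the fatty acid library at its end, and the second held 24.5% with the cholesterol library at its end.

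**Figure D1:**
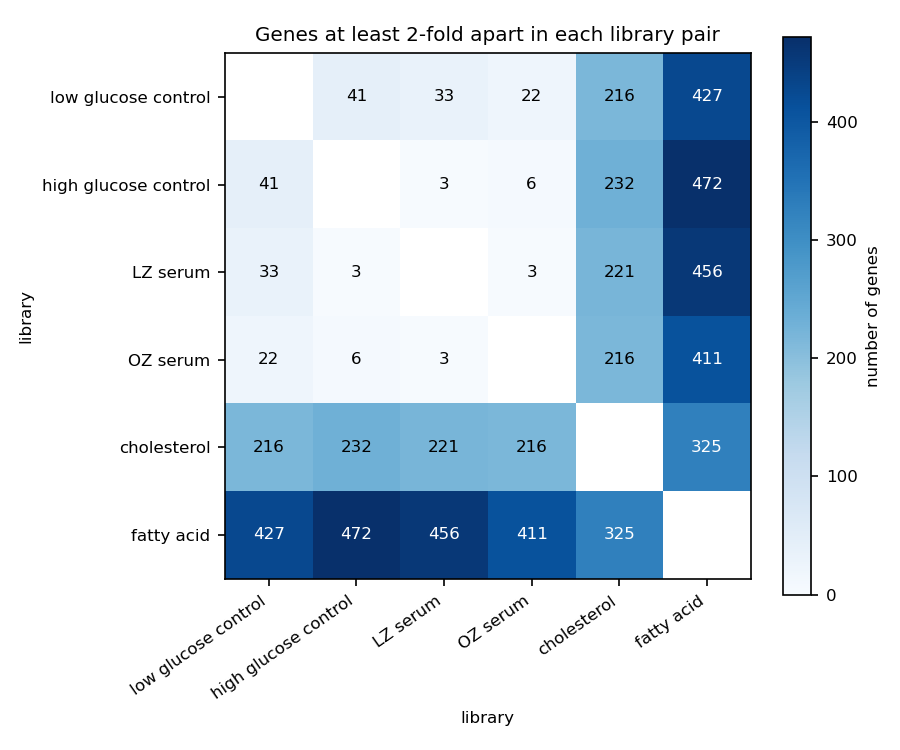
Number of genes, of 11540, that differed at least 2-fold between each pair of the 6 libraries, with 1 array per library on both axes and darker cells for more genes. Pairs that include the fatty acid library lie between 325 and 472 genes, whereas pairs of serum and control libraries lie between 3 and 41.

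The first comparison asks how cells given cholesterol differed from control cells. Sterol export genes were high and sterol synthesis genes were low in the cholesterol library. Abcg1 (probe set 17753937), a transporter that exports cholesterol, was 15.2-fold higher than in either control at the least, at a log2 signal of 11.65 against 7.73 in the high glucose and 7.54 in the low glucose control. Abca1, which loads cholesterol onto apolipoprotein A-I, was 7.27-fold higher. Idi1 (probe set 17720423), the isopentenyl diphosphate isomerase of the mevalonate pathway, was 9.05-fold lower, and Cyp51, the lanosterol demethylase, was 5.14-fold lower. The Idi1 signal with cholesterol, log2 6.72, lay below the median of all values, 6.74, so the size of its fold is less certain. Each fold is the smaller of the differences from both controls. In all, 44 genes were at least 2-fold higher and 93 at least 2-fold lower than in both controls.

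Among targets of SREBP2, the transcription factor that drives cholesterol synthesis and uptake, all 19 measured genes were lower than in both controls and 11 were at least 2-fold lower. Examples are Msmo1 (log2 difference -1.87), Insig1 (-1.60) and Sqle (-1.57), the squalene epoxidase. The list's median was -1.10 against the high glucose and -1.24 against the low glucose control, at percentile 0 of 10000 random lists matched on signal in both cases. Of 13 measured targets of LXR, the sterol-sensing nuclear receptor, 4 were at least 2-fold higher and 1 was at least 2-fold lower. Besides both transporters, the higher genes were Srebf1 (1.54) and Mylip (1.32), which encodes a ubiquitin ligase, while Scd, a stearoyl-CoA desaturase, was lower (-1.52). The LXR median was 0.44 and 0.53 against the controls, at percentile 100 for both, and its size moved with the signal filter, from 0.164 without one to 0.882 with a stricter one against the high glucose control. In fatty acid synthesis and desaturation, 1 of 14 genes was at least 2-fold higher and 3 were at least 2-fold lower, with Fads2 at -1.30 and Acss2 at -1.12, the latter under 2-fold with an offset of 32 before log2.

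Outside lipid metabolism, the gene with the second largest positive difference was Lilrb4, an inhibitory receptor known from myeloid cells, at 9.39-fold. Its control signals, 6.95 and 6.16, lay around the median of all values, so the size of this fold and the rank are less certain, and with an offset of 32 before log2 the difference was 2.94 instead of 3.23. It was followed after Abca1 by Sfrp2, a secreted modulator of Wnt signalling (6.69-fold), and Tlr2, a receptor for bacterial lipoproteins (5.56-fold). Ndrg1 (4.29-fold), Pla2g2a (3.43-fold), a secreted phospholipase, Tslp (3.39-fold), a cytokine, and Cx3cl1 (3.09-fold), a chemokine, were also among the 12 largest. The inflammatory and NF-kB list had a median of 0.58 and 0.67 with 13 of 17 genes higher than in both controls, although only Cxcl1 (1.37) reached 2-fold. Of 7 measured macrophage and leukocyte markers, only Cd68 reached 2-fold (1.56), and the list's median was 0.07 and 0.10, at percentiles 72.9 and 87.6. Lysosome and autophagy genes had medians of 0.17 and 0.33 with 12 of 18 higher and none at 2-fold. The oxidative stress list had medians of 0.17 and 0.27, with 1 of 22 genes at 2-fold, the metallothionein Mt2A (1.27). Of 24 immediate early genes, 15 were higher and 6 lower than in both controls, and only Dusp5 (1.05) reached 2-fold. Their medians were 0.31 and 0.15, at percentiles 100 and 99.78.

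Mstn (probe set 17864319), which encodes myostatin, the secreted inhibitor of muscle growth, was 7.38-fold lower in the cholesterol library, at a log2 signal of 6.61 against 9.74 and 9.49 in the controls. This signal also lay below the median of all values. Igfbp3, an insulin-like growth factor binding protein, was 6.21-fold lower, and P3h2, a collagen prolyl hydroxylase, 4.12-fold lower. Cilp, a cartilage matrix protein, Casq2, a calsequestrin, Stc1 and the integrin Itga8 had log2 differences of -2.02, -1.84, -1.83 and -1.80. Of 24 collagen and matrix genes, 20 were lower than in both controls and Col12a1 reached 2-fold (-1.12), with list medians of -0.20 and -0.51. Of 23 ATF4 targets, which serve amino acid supply and the integrated stress response, 18 were lower and 3 reached 2-fold (Slc7a3 -1.33, Aldh1l2 -1.18, Trib3 -1.11), while Atf3 was higher (1.34). The ATF4 medians were -0.61 and -0.87, at percentile 0 for both. Endoplasmic reticulum chaperones had medians of -0.15 and -0.23 with none of 20 at 2-fold. The mitosis list depended on the control, with medians of 0.01 against high and -0.38 against low glucose.

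Of the 28 lists with at least 3 measured genes, 5 lay above and 6 below the middle 95% of random lists against both controls. Such percentiles treat genes as independent. Between the controls themselves 8 lists lay outside that range, and 12 did between OZ and LZ serum. Each of these counts rests on a single comparison, whereas the cholesterol counts asked for agreement against both controls. With 1 control in place of both, 75 genes were higher and 157 lower against high glucose, and 91 were higher against low glucose.

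**Figure D2:**
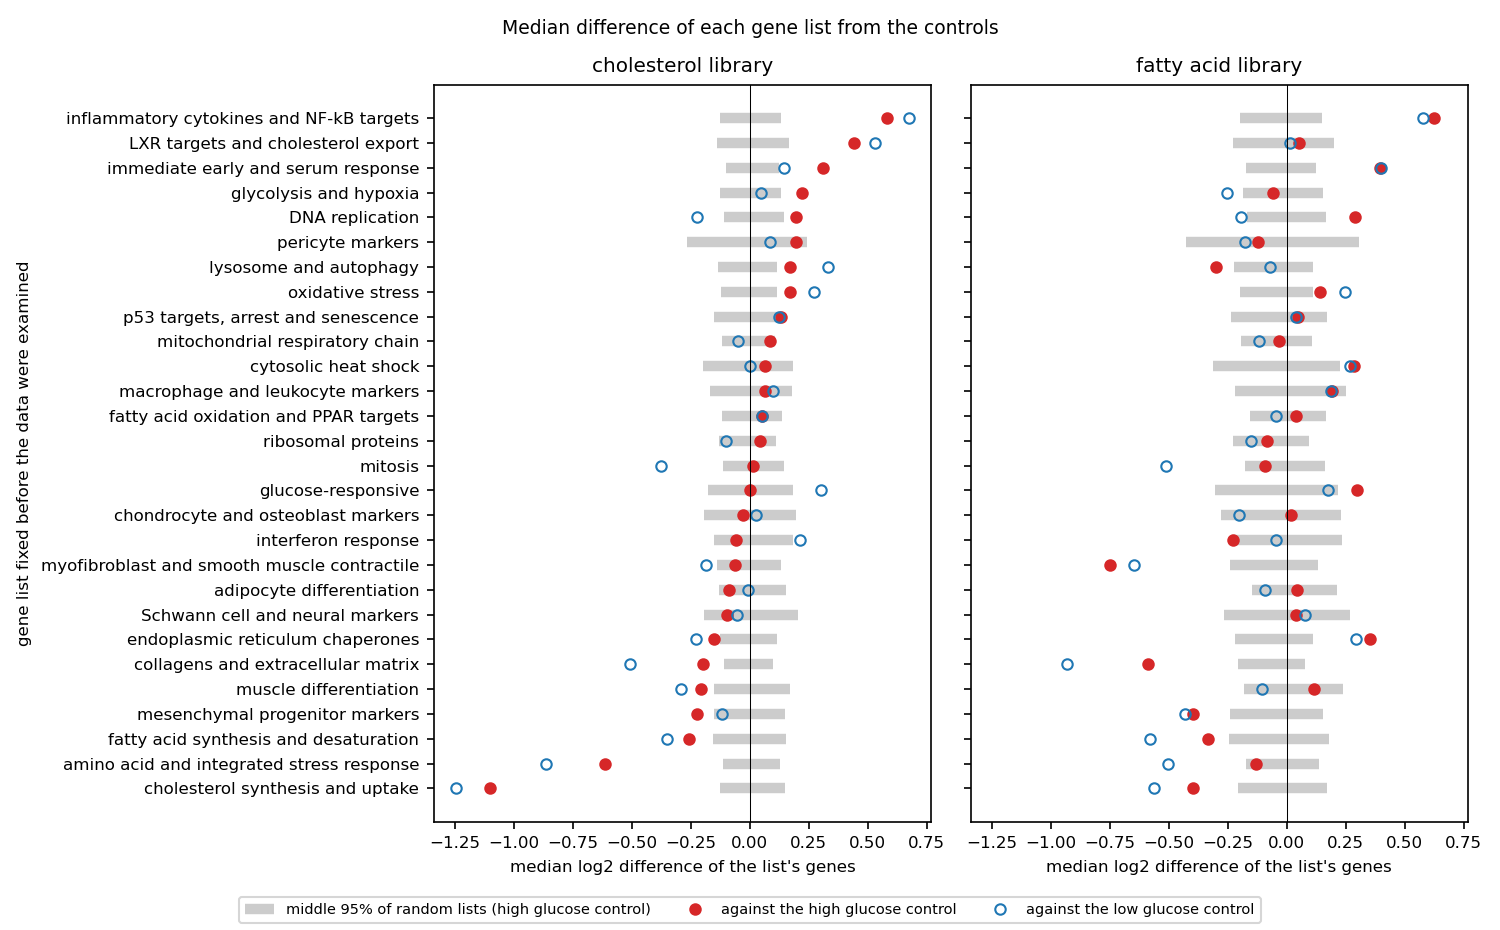
Median log2 difference of each gene list with at least 3 measured genes in the cholesterol (left) and fatty acid (right) libraries, against the high glucose control (filled) and the low glucose control (open), with bars for the middle 95% of 10000 matched random lists against the high glucose control. Cholesterol synthesis and uptake has the lowest medians in the cholesterol library, -1.10 and -1.24, and collagens and extracellular matrix reach -0.59 and -0.93 in the fatty acid library.

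The next comparison asks the same of the fatty acid library. It held 74 genes at least 2-fold higher and 232 at least 2-fold lower than both controls. The largest positive difference was in Crct1 (probe set 17749221), a cysteine-rich gene of the epidermal differentiation complex, at 9.71-fold. Lce1e (7.88-fold), Sprr1a (6.32-fold) and Kprp (4.99-fold), which lie in the same complex and encode proteins of the cornified envelope and keratinocytes, were also among the 12 largest. The control signals of Crct1 (6.94 and 6.39) and Lce1e (6.21 and 6.62) lay near or below the median of all values, so their folds and ranks are less certain, and with an offset of 32 before log2 Crct1 was at 2.983 and Tslp at 2.986. Tslp was 8.81-fold, the neutrophil chemokine Cxcl1 6.38-fold and the stress-induced transcription factor Atf3 4.37-fold higher. Derl3, which takes part in the degradation of misfolded proteins of the endoplasmic reticulum, was 7.28-fold higher, and Lilrb4, with control signals of 6.95 and 6.16, was 5.69-fold higher. The lowest gene was Npr3 (probe set 17745928), the clearance receptor for natriuretic peptides, at 11.6-fold below the nearer control.

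Endoplasmic reticulum chaperones were higher together: 17 of 20 exceeded both controls and 2 reached 2-fold. These were Creld2 (1.40) and Dnajb9 (1.27). The chaperones Dnajc3 (0.70) and Pdia4 (0.65) lay below that threshold, as did Hspa5, or BiP (0.54). The list's medians were 0.35 and 0.30, at percentiles 100 and 99.98. Of 17 inflammatory genes, 15 were higher and 5 reached 2-fold, among them Cxcl1, Mmp3 (1.61), a matrix metalloproteinase, Ccl20 (1.39) and Nfkbiz (1.31), with medians of 0.62 and 0.58. Against the high glucose control, that median was 1.01 under the stricter signal filter. Of 24 immediate early genes, 17 were higher and 7 reached 2-fold, led by the phosphatases Dusp5 (4.15-fold) and Dusp6 (2.83-fold) and the AP-1 subunits Fosl1 (2.82-fold) and Jun (2.34-fold). Jun was under 2-fold when its probe sets were averaged. In the oxidative stress list, 2 of 22 genes reached 2-fold, Hmox1 (1.23), a heme oxygenase, and Srxn1 (1.20). Cytosolic heat shock genes had medians of 0.29 and 0.27 with none of 9 at 2-fold. Of 23 ATF4 targets, 12 were lower and 7 higher than in both controls, with medians of -0.13 and -0.50 at percentiles 7.33 and 0. At 2-fold, 3 were higher and 3 lower, among them Atf3 (2.13) and Ppp1r15a (1.10) higher and Slc7a3 (-2.05) and Aldh1l2 (-1.74) lower.

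Matrix and contractile genes were low in the fatty acid library. Of 24 collagen and matrix genes, 21 were lower than in both controls and 7 reached 2-fold, led by Thbs2 (-1.61), Col4a1 (-1.53), Col11a1 (-1.39) and Loxl1 (-1.11), and the medians were -0.59 and -0.93. Of 14 myofibroblast and smooth muscle genes, 13 were lower and 3 reached 2-fold, Itga8 (-2.39), the actin filament nucleator Lmod1 (-1.09) and the smooth muscle actin Actg2 (-1.04). Actg2 was under 2-fold with an offset of 32 before log2. The list's medians were -0.75 and -0.65, both at percentile 0. In the muscle differentiation list, Acta1, the skeletal muscle actin (-2.07), and Mef2c (-1.06) reached 2-fold, but the medians of the 9 genes were 0.11 and -0.10 and their means -0.36 and -0.39. Mef2c was also under 2-fold with that offset. Outside the lists, Nrep (10.5-fold), Vegfd (10.4-fold), a lymphangiogenic growth factor, Hapln1 (10.4-fold), a link protein of the hyaluronan matrix, P3h2 (10.1-fold), Ogn (8.47-fold), a small proteoglycan, and Pln (7.22-fold), phospholamban, were lower. P3h2 and Pln, at log2 signals of 5.72 and 6.07 with fatty acid, lay below the median of all values, and the offset took their differences from -3.34 to -2.74 and from -2.85 to -2.38. The signals of Nrep, Vegfd, Hapln1 and Ogn were 9.09, 7.35, 7.59 and 9.52. Of 13 mesenchymal progenitor markers, 10 were lower with medians of -0.40 and -0.43, and none reached 2-fold.

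Among lipid genes of the fatty acid library, sterol synthesis was low by less than with cholesterol. Of 19 SREBP2 targets, 17 were lower, 1 at least 2-fold (Dhcr7, -1.21), with medians of -0.40 and -0.56. In fatty acid synthesis, 11 of 14 genes were lower and Elovl6, a fatty acid elongase, reached 2-fold (-1.14). Of 21 genes of fatty acid oxidation and PPAR targets, only Ucp2 reached 2-fold (-1.38). In that list Cpt1a, which brings fatty acids into mitochondria, was at 0.95 and the lipid droplet gene Plin2 at 0.76, and the list's medians were 0.04 and -0.04 (means 0.03 and 0.03). Among LXR targets Abcg1 was higher (1.56) and the phospholipid transfer protein Pltp lower (-1.16). In the interferon list Cxcl10 (1.89) and Usp18 (1.86) were higher and Ifit2 lower (-1.07), with medians of -0.23 and -0.05 and means of 0.01 and 0.19. Against the high glucose control alone, 118 genes were higher and 354 lower. Medians of 7 macrophage and leukocyte markers were 0.19 against each control, with none at 2-fold.

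**Figure D3:**
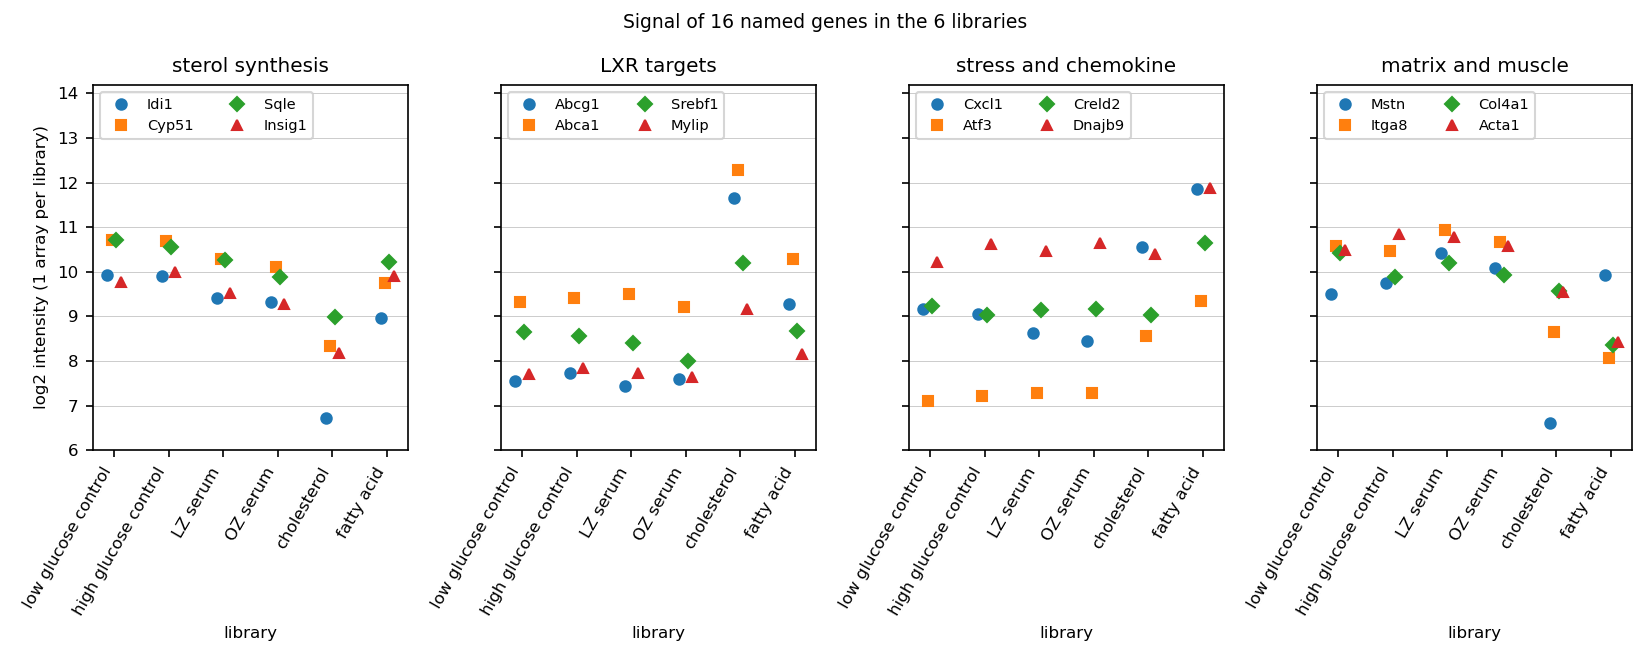
Log2 intensity of 16 named genes in the 6 libraries, where each point is 1 array and there are no error bars because each library has 1 array. Abcg1 reaches 11.65 and Idi1 6.72 in the cholesterol library, Cxcl1 and Dnajb9 are highest in the fatty acid library, and Mstn is low (6.61) in the cholesterol library only.

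The lipid libraries shared genes in both directions. To keep any control from entering both sides, cholesterol was set against the high glucose control and fatty acid against the low glucose control. At 2-fold, 26 genes were then higher in both, where independent lists would share 0.715, and 81 were lower in both, where independent lists would share 4.31. With the controls exchanged, 20 genes (0.931 for independent lists) and 69 genes (3.83) were shared. The correlation of the differences across 11540 genes, which are not independent replicates, was 0.309 and 0.312. When both lipids were read against both controls, 15 genes were higher and 50 lower in both. Shared controls may add to such an overlap, but by the counting rule each of these genes is also shared in both pairings with separate controls. The shared higher genes included Abcg1, Lilrb4, Tslp, Cxcl1, Atf3, Usp18 and Fgf7, a fibroblast growth factor. The shared lower genes included Igfbp3, P3h2, Cilp, Itga8, Ogn, Npr3 and Hapln1.

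Compared directly, the cholesterol library held 221 genes at least 2-fold higher and 104 at least 2-fold lower than the fatty acid library. Sfrp2 was 10.5-fold higher in the cholesterol library, the carbonic anhydrase Car3 6.68-fold, Vegfd 6.65-fold, Cx3cl1 5.39-fold, Tlr2 5.29-fold and Abcg1 5.15-fold. Kprp was lower by the most (log2 difference -3.32), followed by Mstn at 9.96-fold, Derl3 at 9.49-fold and Serpinb2, an inhibitor of plasminogen activators, at 8.68-fold lower. Kprp and Serpinb2 were also over 2-fold apart between the controls. Mstn in the fatty acid library lay above both controls, by 0.19 over the nearer of them. SREBP2 targets were lower with cholesterol in 17 of 19 cases, 6 of them at 2-fold, including Insig1 (-1.74) and Msmo1 (-1.71), with a median of -0.70. LXR targets were higher in 11 of 13 cases, 5 at 2-fold, with a median of 0.51, while Scd was lower at 2-fold (-1.01) but not with an offset of 32 before log2. Endoplasmic reticulum chaperones were lower in 19 of 20 cases, 4 at 2-fold (Creld2 -1.61, Dnajb9 -1.50, Dnajc3 -1.17, Pdia4 -1.06), with a median of -0.43. Myofibroblast genes (median 0.50), glycolysis and hypoxia genes (0.46) and matrix genes (0.29) were higher with cholesterol. In the hypoxia list, the carbonic anhydrase Car9 (1.80), Egln3 (1.49) and Ndrg1 (1.20) reached 2-fold. Against both controls, Car9 was lower with fatty acid (-2.31) and Ndrg1 was higher with cholesterol (2.10), while Egln3 differed between the controls (1.31). The hypoxia list's medians against the high and low glucose controls were 0.22 and 0.05 with cholesterol and -0.06 and -0.25 with fatty acid. Of 17 inflammatory genes, 12 were lower and 5 higher with cholesterol, with a median of -0.35 at percentile 0.02. Mmp3 (-1.58) and Cxcl1 (-1.30) were lower and Il6 (1.22) and Mmp9 (1.02) higher at 2-fold, although Mmp9 was under 2-fold after quantile normalization and with an offset of 32 before log2. Il6 also differed between the controls (1.13).

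The serum libraries, titled LZ and OZ, were close to each other. In the OZ serum library 0 genes were at least 2-fold higher and 3 were at least 2-fold lower than in the LZ serum library: Mt2A (-1.28), Wfdc18 (-1.12) and Cdo1 (-1.01), a cysteine dioxygenase. With a stricter signal filter 1 of the 3 remained, and with an offset of 32 before log2 only Mt2A did. Smaller differences ran through whole lists. All 22 mitosis genes were higher in the OZ serum library, with a median of 0.27 and Bub1 (0.54), Cdc20 (0.37) and Top2a (0.36) as examples, and 17 of 21 replication genes were higher (median 0.13). SREBP2 targets were lower in 18 of 19 cases (median -0.16; Tm7sf2 -0.53, Lss -0.49), and so were 12 of 14 fatty acid synthesis genes (-0.19) and 23 of 24 matrix genes (-0.10). Pdk4, a kinase that restrains pyruvate oxidation, was at 0.64 and Cxcl10 at 0.78.

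Between the controls, 29 genes were at least 2-fold higher and 12 at least 2-fold lower in high glucose. Ampd3 (probe set 17619561), an AMP deaminase, was 3.71-fold higher. The small proteoglycans Lum (3.21-fold) and Aspn (3.21-fold), Itm2a (2.90-fold), Acod1 (2.88-fold), which makes itaconate, and Serping1 (2.52-fold), the C1 inhibitor, were among the 12 largest. Serpinb2 was 4.98-fold, Serpinb7 3.49-fold, the collagen Col6a3 2.79-fold and Tgfbi 2.21-fold lower. All 22 mitosis genes were lower in high glucose (median -0.41; Prc1 -0.74, Plk1 -0.67), as were 19 of 21 replication genes (median -0.43; Mcm5 -0.75) and 12 of 14 fatty acid synthesis genes (median -0.36). All 18 lysosome genes were higher with a median of 0.19, and 10 of 11 interferon genes were higher with a median of 0.23. None of these list members reached 2-fold. Il6 (1.13) and Egln3 (1.31) did. In the glucose-responsive list, Txnip, which glucose is known to induce, was at 0.79, and the median of the 10 genes was -0.07.

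Set against both controls, the serum libraries held 0 genes at least 2-fold higher and 0 at least 2-fold lower in both. With the low glucose control alone, 8 genes were higher and 5 lower. All 19 SREBP2 targets were nevertheless lower in both serum libraries than in both controls, with medians of -0.22 and -0.35 for LZ serum and -0.47 and -0.61 for OZ serum against the high and low glucose controls. Hsd17b7 (-0.55), Idi1 (-0.49) and Cyp51 (-0.40) had the largest differences, and 10 of 14 fatty acid synthesis genes were also lower. Fatty acid oxidation and PPAR targets were higher in 10 of 21 cases and lower in 4, with Cpt1a at 0.44 and Acadl, an acyl-CoA dehydrogenase, at 0.28. Mitosis genes followed no common direction: the median was 0.13 for LZ serum and 0.45 for OZ serum against high glucose, and -0.30 and 0.02 against low glucose, where the OZ mean was -0.02.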

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

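The offset of 32 before log2 and the agreement with the serum libraries were chosen after seeing the data. No paired analysis was possible because each group has 1 library. None of the list medians and named genes recomputed here changed sign. Of the counts of genes, 95 stayed within 1.5 times and 27 did not. Of list medians 158 moved by less than 0.1 and 10 by more, and of named gene differences 329 and 70. With the offset of 32, Acss2 and Dusp5 for cholesterol, Mef2c and Actg2 for fatty acid and Wfdc18 and Cdo1 for OZ against LZ serum were under 2-fold, as were 8 named genes for cholesterol against fatty acid, Mmp9 among them, and 2 for high against low glucose. The offset moved named gene differences by up to 0.346 for cholesterol and 0.601 (P3h2) for fatty acid. Quantile normalization, median centring, cyclic loess and averaging of probe sets moved none of the gene counts by over 1.5 times. At a 1.5-fold threshold, which admits more genes by construction, counts higher and lower were 157 and 235 for cholesterol, 337 and 707 for fatty acid, 857 and 497 for cholesterol against fatty acid, 13 and 17 for OZ against LZ serum, 184 and 128 for high against low glucose, and 1 and 1 for serum against controls. With the high glucose control alone, which asks for 1 comparison instead of 2, cholesterol had 75 higher and 157 lower genes and fatty acid 118 and 354. With the low glucose control alone cholesterol had 91 higher genes, and the serum libraries had 8 higher and 5 lower. Against the mean of the controls cholesterol had 71 higher genes and the serum libraries 2 lower. With OZ serum alone, 1 gene was higher and 1 lower than both controls. For OZ against LZ serum, which had 0 higher and 3 lower genes, 9 were higher and 6 lower without a signal filter, so that more were higher than lower, and 1 was lower with the stricter filter and 1 with the offset of 32. Without a filter, LXR medians in the cholesterol library were 0.164 and 0.234 (high and low glucose control), and 0.882 and 0.994 with the stricter filter. Inflammatory medians without a filter were 0.524 for cholesterol against low glucose and 0.490 for fatty acid against high glucose, and with the stricter filter 1.005 and 0.920 for fatty acid. Myofibroblast medians for fatty acid against low glucose were -0.498 and -0.798. These filters change which genes a list holds, and the cause was not tested further. When agreement with the serum libraries was also asked, 38 of 44 higher and 75 of 93 lower genes were kept for cholesterol, and 71 of 74 and 190 of 232 for fatty acid. Differences of genes near the median signal of 6.74 are limited by signal over background, which was not measured.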

Other observations

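The tests of the cornified envelope and macrophage gene patterns were chosen after the result was seen, and the bounds of the serum and glucose tests were written before. Genes in the paragraph on plasma proteins and metallothioneins were picked after their values were seen.

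C3, the central complement protein, had its highest log2 signal in the cholesterol library (11.12) and its lowest in the low glucose control (9.22), with 10.28 in the high glucose control, 10.28 with fatty acid, 10.49 in LZ serum and 9.93 in OZ serum. Cp, or ceruloplasmin, was at 9.61 with cholesterol, 9.36 in LZ serum, 8.99 in high and 8.04 in low glucose, and lowest with fatty acid (7.29). Lbp, the lipopolysaccharide binding protein, was at 8.54 in LZ serum and 7.63 in OZ serum, and at 6.92 both with fatty acid and in low glucose. The metallothionein Mt2A was highest with cholesterol (12.61), then fatty acid (11.96), LZ serum (11.77), low glucose (11.34), high glucose (10.68) and OZ serum (10.49). Mt1 was highest with cholesterol (10.47), then fatty acid (10.36), and lowest in OZ serum (8.62).

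Crct1, Lce1e, Sprr1a and Kprp, genes of the cornified envelope of skin, were high in the fatty acid library, at log2 signals of 10.22, 9.59, 9.68 and 11.02; they were picked from the 12 genes furthest above both controls, and the cornified envelope genes Ivl (0.07) and Flg (0.05), at low signal, were near the mean of the controls. Keratinocytes numerous enough to raise their genes together are argued against by 19 other keratinocyte genes, of 25 listed, Ivl and Flg included. Their median difference from the mean of the controls was 0.153, below the 0.5 set as a bound. The 95% bootstrap interval, 0.030 to 0.200, resampled genes within 1 array and does not measure differences between cultures. Krt14 was at 0.42, Krt10 at -0.10, Pkp1 at 1.28 and Jup at -1.27. Pkp1 (10.01) and Jup (10.81) already had high control signals, so they say little about keratinocytes. Others, such as Krt14 (6.61) and Dsg3 (5.44), had control signals below the median of all values. A small share of keratinocytes was therefore not excluded. A scaling that depends on signal would move genes of equal signal alike. The 200 genes nearest each of the 4 in control signal had median differences of 0.070 at most, where the 4 differed by 2.696 or more. Genes of equal signal thus shared no shift of that size, for which the nearly equal distributions of the arrays left little room. The upper ends of the neighbours' middle 95% were 0.671 at most. The 4 were picked for large differences, so lying above their neighbours was set by the choice. Kprp also differed between the controls (8.70 in high and 7.22 in low glucose). A response of the cells to palmitate may underlie the pattern, a hypothesis that 1 library cannot separate from a difference between cultures.

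Lilrb4, Tlr2, Cd68 and Lgals3, known from macrophages, were high in the cholesterol library, at log2 signals of 10.18, 9.97, 8.37 and 12.30. Leukocytes numerous enough to raise their genes together are argued against by the 15 genes of the fixed macrophage and leukocyte list, Cd68 included. Their median difference was 0.045, with a bootstrap interval over genes of 0.001 to 0.160. Cd14 was at 0.81, Tyrobp at 0.16, Ptprc at -0.10 and Lyz2 at -0.23. Only 7 of the 15 passed the signal filter. Others, such as Ptprc (5.52) and Lyz2 (5.13), had control signals below the median of all values. A small share of leukocytes was therefore not excluded. For scaling that depends on signal, the 200 genes nearest each of the 4 in control signal had medians of -0.001 at most. The 4 differed by 1.464 or more, so genes of equal signal shared no shift of that size. Here too the nearly equal distributions of the arrays left little room for one. The middle 95% of these neighbours ended at 0.349 for Cd68 and 0.494 for Lgals3, the genes with the smallest differences of the 4. The 4 were picked as high, so lying above their neighbours was set by the choice. Lilrb4 was also higher than both controls in the fatty acid library (2.51), where Tlr2 was at 0.07, Cd68 at 0.40 and Lgals3 at -0.36, so its difference is not specific to cholesterol. For the other 3 genes a change in the stem cells themselves under cholesterol, or under its cyclodextrin carrier, may underlie the pattern and was not tested.

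The mitosis and replication lists were higher in OZ than LZ serum and in low than high glucose, which raised the hypothesis that both pairs differ along the same axis across all genes. Across all genes the pairs followed each other only weakly, although most genes differed little in either pair. Of the 3 genes at 2-fold between the serum libraries, Wfdc18 (-1.43) and Cdo1 (-1.05) were also lower in low than in high glucose. Mt2A went the other way, with a high minus low glucose difference of -0.66. The correlation of the OZ minus LZ with the low minus high glucose differences was 0.061 across 11540 genes and 0.063 after the trend with signal was removed. It was 0.003 across the 11092 genes left without those tied to growth. The removed genes were picked in these same 6 libraries, by a growth mean that differs within both pairs. Their removal by itself favours such a fall. The starting correlation was already under the bound of 0.1, so neither test could decide between scaling and the growth state of the cultures. The mean of the 43 mitosis and replication genes, relative to the 6 libraries, was highest in low glucose (0.246) and OZ serum (0.134) and lowest in high glucose (-0.174).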
